A study of Homo sapiens with 12 samples.

How the data were processed

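Transcript levels were measured with Affymetrix oligonucleotide arrays in HMT-3522 S1 cells, an established non-neoplastic human mammary epithelial line that forms acini in basement membrane gel. Per the labels' protocols, cells at passage 55 to 60 were plated at 35000 per cm2 and grown with 5% Matrigel for 10 days, the last 48 hours without EGF after 8 days with it. The 3 groups of 4 arrays compared were labelled vehicle (apically polarized), AGA and Aza (neither polarized). AGA is 18-alpha-glycyrrhetinic acid, an inhibitor of gap junction communication, and Aza is 5-aza-2'-deoxycytidine, an inhibitor of DNA methyltransferases. Both were given at 10 µM from plating for 10 days with a medium change every 2 days. The series design calls the replicates biological, and no label says more about how separate the cultures were. The p-values therefore measure variation between replicates of this cell line.

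The deposited values are intensity per probe set on a linear scale, from 0.0206 to 11878. Per the submitters' processing notes they were made with GCOS, the Affymetrix operating software, with no version or algorithm stated. Per the labels' protocols, 2.25 µg of RNA per sample was labelled, with 1 sample per array. The deposited medians per array ran from 23.3 to 35.9, which shows no common level, and whether the arrays were scaled at all is not recorded. Detection calls were not used here, so the number of arrays limits the precision, and 5.26% to 7.94% of values per array lay below an intensity of 1.

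Values below 1 were set to 1 and log2 was taken. The medians of the 12 arrays then differed by 0.62, more than the limit of 0.5 set in advance, so the arrays were quantile normalized with limma. The 62 control probe sets were left out of the 22277, leaving 22215. Of these, 19064 carried 1 gene symbol in the platform annotation, 1043 carried several and 2108 none; 19052 matched the gene table of assembly GRCh38.p14, which changed 0 symbols. The files name no genome build, so no coordinates are given. The symbols covered 11963 genes, and none was taken from a probe set with several.

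Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all 12 arrays, so that the 3 groups shared 1 estimate of the spread. Benjamini-Hochberg adjustment covered all probe sets at a threshold of 0.05. The 4 contrasts were AGA against vehicle, Aza against vehicle, Aza against AGA, and the mean of both treatments against vehicle (not polarized against polarized). For comparisons sharing the vehicle arrays, the correlation, covariance and overlap of changes were set beside 40 simulations of unchanged groups and beside vehicle arrays or pairs split 2 and 2.

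Gene lists were tested with limma's camera at its preset correlation of 0.01, with the brightest probe set per gene, adjusted over the lists of each comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run beside it; mixed fry asks the same for change in either direction. The 34 lists covered cell polarity and adhesion (apical polarity complexes, tight junction, adherens junction, desmosome, hemidesmosome and basement membrane, gap junction); DNA methylation machinery, cancer testis and germline genes, and imprinted genes; interferon response and MHC class I antigen presentation; p53 targets, mitosis, S phase, cell cycle inhibitors and histones. They also covered NRF2, endoplasmic reticulum stress and amino acid, heat shock and glucocorticoid responses; cholesterol synthesis, glycolysis, oxidative phosphorylation and ribosomal proteins; NF-kB, EGFR and immediate early, and TGF-beta responses. Mesenchymal, luminal, basal, squamous, fibroblast, leukocyte, and endothelial and adipocyte markers completed them.

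Whether replicate numbers pair the samples was checked on deviations from the group means. Arrays of different groups with the same number correlated in 12 of 12 pairs over 0.1 (0.368 to 0.781), against 0.181 at most for different numbers, so the numbers were treated as pairing the samples. The labels give only the numbers; the pairing comes from the data. A fit with the number as a replicate block was an alternative listed in advance. A fit with the block and an intensity trend in the prior variance (eBayes, trend and robust) was added after seeing the data.

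The lists, contrasts, thresholds, normalization rule and rule for naming genes were fixed before the data were examined. The rule named, per comparison, the 12 genes with the largest rise and fall (8 for Aza against AGA and for both treatments) among those past the threshold. The 4 treated values had to lie on 1 side of the 4 vehicle values and the higher mean above the median level. Where under 5 probe sets passed, it named the 5 lowest p per direction, as values only. The text departs from this for probe sets past the adjusted threshold, which are said to rise or fall. The rule added up to 4 members with the lowest p per list, and GJA1, DNMT1, DNMT3A, DNMT3B, HSD11B1, HSD11B2, PARD3, TJP1, CDH1, ITGB4, MKI67 and CDKN1A. GJB2 was also on it but has no probe set with a single symbol. Genes from the fit with block and trend were chosen after their values were seen. They were the 8 largest changes per direction and members of groups named in the text. The 8 were taken only among genes whose higher mean lay above the median level and whose 4 same-number pairs all changed the same way. Dim probe sets with larger changes were thus left out of the 8.

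The alternatives were the deposited scale, median-centred arrays, leaving out probe sets below the median level, a floor at the 20th percentile, an intensity trend, Holm adjustment, a threshold of 0.01, fitting only the 2 groups compared, the replicate block, the mean of a gene's probe sets, and leaving out each array. Those added after seeing the data combined the block with the trend or filter, left out all replicate 4 arrays, or split same-number pairs. The fits were tested on simulated data for AGA against vehicle, over 22215 probe sets with the real levels and spread. Without the block they recovered 84.7% of 4-fold changes of the signal above the median level and 10.8% below it, and 24.3% and 1.59% of 2-fold changes. With block and trend, 98.8% and 15.5% of 4-fold and 72.8% and 1.39% of 2-fold changes were recovered. In 20 simulations of independent unchanged genes camera called 0 lists in AGA against vehicle, and a rise of 0.5 in the NRF2 list was called in 20. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.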

Results

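RNA from HMT-3522 S1 mammary epithelial acini was hybridised to 12 single-colour arrays. Of these, 4 came from vehicle cultures, which the labels call apically polarized. Another 4 came from cultures given the gap junction inhibitor AGA and the last 4 from cultures given the DNA methyltransferase inhibitor Aza, both called non-polarized. Median deposited intensity per array ran from 23.3 to 35.9, and the number of arrays limits the precision. All levels below are log2 intensities after quantile normalization, with a floor of 0.

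The first principal component held 43.4% of the variance and separated the replicate 4 arrays of all 3 groups (38.7 to 46.3) from the other 9 (at most -7.32). A share of 0.00601 of its variance lay between the groups. Replicate number was therefore the larger source of difference, and values that take it into account are given where they change a call.

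**Figure D1:**
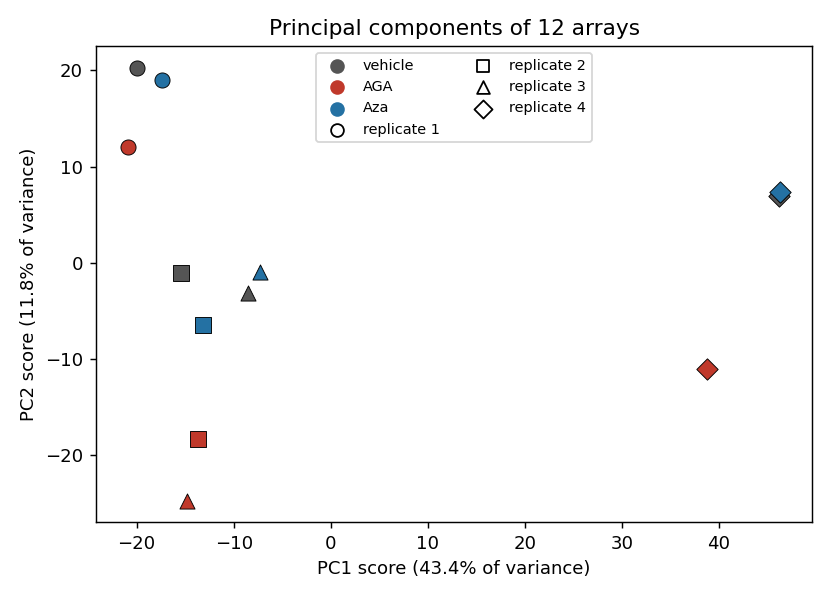
Scores of the 12 arrays on the first (43.4% of variance) and second (11.8%) principal components, in arbitrary units; colours mark the 3 groups and symbols the replicate number. The 3 replicate 4 arrays lie at 38.7 or above on the first component, and the other 9 at -7.32 or below.

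The comparison of AGA with vehicle asked which transcripts differ when polarity is lost under blocked gap junctions. CYP1B1, a cytochrome P450 that oxidises oestrogens and aromatic hydrocarbons, rose from 0.32 ± 0.50 to 3.88 ± 0.68 (SD, n = 4), by 3.56 ± 0.34 (SE; limma adjusted p = 0.00722). KCNJ1, which encodes the potassium channel ROMK, rose from 0.30 ± 0.51 to 3.10 ± 0.08 (SD, n = 4), by 2.80 ± 0.23 (SE; limma adjusted p = 0.00242). Both were higher in 4 of 4 same-number pairs, and both started near the floor. The 3 brighter CYP1B1 probe sets differed by only 0.58, 0.94 and 0.72, and another KCNJ1 probe set by 1.10, none passing in this fit. Next by p among higher values were the cytokine receptor CRLF2 (2.02), the nucleoside transporter SLC29A1 (1.85) and the semaphorin receptor NRP1 (2.42), at limma adjusted p of 0.0859, 0.111 and 0.159. Among lower values they were the transcription factor ONECUT2 (-1.68, adjusted p = 0.159), the calcium-binding CASQ1, at the floor on every AGA array (-2.23, 0.255), the laminin LAMB4 (-2.57, 0.314), the olfactory receptor OR2W1 (-2.05, 0.718) and the ephrin receptor EPHA7 (-1.89, 0.808). Other probe sets of SLC29A1 (-0.36), NRP1 (0.16 and -0.18) and LAMB4 (1.08) were near 0 or on the other side.

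None of the genes chosen in advance passed in AGA. GJA1, the connexin 43 gene, differed by 0.11 ± 0.36 (SE, n = 4). HSD11B1 and HSD11B2, the glucocorticoid-converting enzymes that glycyrrhetinic acids inhibit, differed by -1.13 ± 0.81 and 1.39 ± 0.70. The polarity and junction genes PARD3 (-0.09), TJP1 (0.01), CDH1 (-0.11) and ITGB4 (0.35) also had limma adjusted p of 1, as did the proliferation marker MKI67 (0.39) and the cell cycle inhibitor CDKN1A (0.05). In all, 2 of 22215 probe sets passed, 2 higher and 0 lower (limma), with 1051 at an unadjusted p under 0.05, 523 of them lower, where chance gives 1110.8. The unadjusted count was 2115 with the replicate block and 2612 with block and trend, both above that number. Leaving out vehicle 2, vehicle 3, vehicle 4 or AGA 2 ended the CYP1B1 call (adjusted p of 0.0512 to 0.0537) and left 1 probe set, whereas 4 passed without vehicle 1 or without Aza 1 and 5 without AGA 4; CRLF2 passed without AGA 1 (0.034), NRP1 without Aza 1 (0.0217), CASQ1 without vehicle 1 (0.0146) and OR2W1 without AGA 4 (0.0111).

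Camera called 5 of 34 gene lists in AGA, all higher. MHC class I antigen presentation genes, which load and display peptides, were higher in AGA by a median of 0.48 in 16 of 16 members (camera adjusted p = 4.5e-08; adjusted p = 0.433 with an estimated correlation). Targets of the oxidative stress factor NRF2 had a median of 0.47 (23 of 27 members above 0, 2.7e-06) and interferon response genes 0.44 (38 of 45, 1.2e-04), each with adjusted p = 0.433 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.14 (37 of 40, 1.2e-04), and genes of the endoplasmic reticulum stress and amino acid response 0.19 (23 of 27, 0.00261), again with adjusted p = 0.433 with an estimated correlation. None of the 5 therefore held there, and 9 of 35 ways of dividing the 8 arrays gave 5 or more lists. The MHC members with the lowest p were the peptide-loading factor TAPBP (0.63 ± 0.23, SE, n = 4), HLA-G (0.61), and the immunoproteasome subunits PSMB9 (1.74) and PSMB10 (0.56). In the interferon list they included the RNA sensor IFIH1 (2.01) and LAMP3 (1.71), with IRF9 on the other side (-0.53). In the NRF2 list they were the reductase TXNRD1 (0.76 ± 0.19), haem oxygenase HMOX1 (1.09 ± 0.42), the NADPH suppliers ME1 (0.56) and PGD (0.45). The stress list was led by TRIB3 (1.05 ± 0.32), SLC3A2 (0.64), PHGDH (0.72) and the cystine transporter SLC7A11 (0.93), and the respiratory list by NDUFA1 (0.60), COX6C (0.31), COX7C (0.25) and CYC1 (0.27).

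Members were also counted for the 5 lists and the others. Over all probe sets limma called 0 members of the 5 lists without the block, and 0 adjusted over the list alone; unadjusted counts were 1051 over all probe sets. With the replicate block, 11 NRF2 members passed adjusted over the list alone, all higher, as did 6 glucocorticoid response genes higher and 1 lower. The glucocorticoid list holds metal-binding metallothionein genes such as MT1G, MT1X and MT1F. Their probe sets can cross-hybridise within the family, so they need not be separate measurements. THBS1 in the TGF-beta list was lower, P4HA2 in the glycolysis list and KRT16 in the basal list were higher, and MYH11 in the basal list was lower. Outside the 5, the connexin GJB5 (1.19 ± 0.30, SE, n = 4) passed adjusted over the list alone (adjusted p = 0.0231, limma; 0.0697 with the replicate block), as did IGFBP7 among the cell cycle inhibitors (0.0479; 0.0683 with the block). The replicate block added EGFR and immediate early genes, lower by a median of -0.27 (camera adjusted p = 0.043 with the block, 0.268 without; adjusted p = 0.558 with an estimated correlation and the block). That list also passed, lower, without vehicle 4 (6.6e-04) and without AGA 1 (0.00529); desmosome genes passed without vehicle 2 (0.0193) and cholesterol synthesis genes without AGA 4 (0.00443). The stress list was not called without vehicle 4 (0.129). On the deposited scale the median of all genes was -0.24 in AGA minus vehicle. Relative to it the MHC list was at 0.45, NRF2 at 0.44, interferon at 0.40, stress at 0.17 and respiration at 0.16, the last 2 being below 0 in absolute terms there, and respiration was not called (0.193). Limma's fry called 0 lists without the block, and with it the respiration list (adjusted p = 0.00151) and the glucocorticoid list (0.049).

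Camera did not call the junction and polarity lists, which the study's aim concerns, in AGA. Median differences were -0.04 for apical polarity complexes (camera adjusted p = 0.886), -0.19 for tight junction (0.296), -0.03 for adherens junction (0.723), 0.19 for desmosome (0.174; below 0 on the deposited scale), 0.00 for hemidesmosome and basement membrane (0.723) and 0.40 for gap junction genes (0.174). Mixed fry, which asks for change in either direction, called 0 lists without the block and 17 of 34 with it, including tight junction (adjusted p = 0.00283), desmosome (0.0029), hemidesmosome and basement membrane (7.3e-04) and gap junction genes (0.0373). Apical polarity complexes (mixed fry adjusted p = 0.065) and adherens junction (0.515) did not pass with the block. Lists outside polarity and adhesion passed as well, such as oxidative phosphorylation (1.9e-06), so these calls were not particular to junctions. TJP3, a tight junction scaffold, was 1.97 lower in value (-1.97 ± 0.53, SE, n = 4), with limma adjusted p of 0.0541 adjusted over the list alone. Growth lists had medians of -0.12 for mitosis (0.271), -0.06 for S phase (0.296), -0.04 for cell cycle inhibitors (0.694), 0.01 for p53 targets (0.865) and 0.10 for histones (0.723). Stress and metabolic lists had 0.13 for glucocorticoid response (0.174; below 0 on the deposited scale, and 0.23 on median-centred arrays, adjusted p = 0.0122), 0.15 for cholesterol synthesis (0.174), 0.08 for glycolysis (0.271) and -0.09 for heat shock (0.644), and ribosomal protein genes -0.01 (0.723), or 0.19 on median-centred arrays (3.7e-08). Signalling lists had 0.23 for NF-kB (0.467) and 0.04 for TGF-beta (0.723). Epigenetic lists had -0.02 for methylation machinery (0.644), -0.11 for cancer testis (0.354) and -0.12 for imprinted genes (0.644). Cell type lists had 0.00 for mesenchymal (0.723), 0.05 for luminal (0.694), 0.01 for basal (0.835), 0.00 for squamous (0.723), -0.17 for fibroblast (0.296), 0.00 for leukocyte (0.966) and 0.18 for endothelial and adipocyte markers (0.965).

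**Figure D2:**
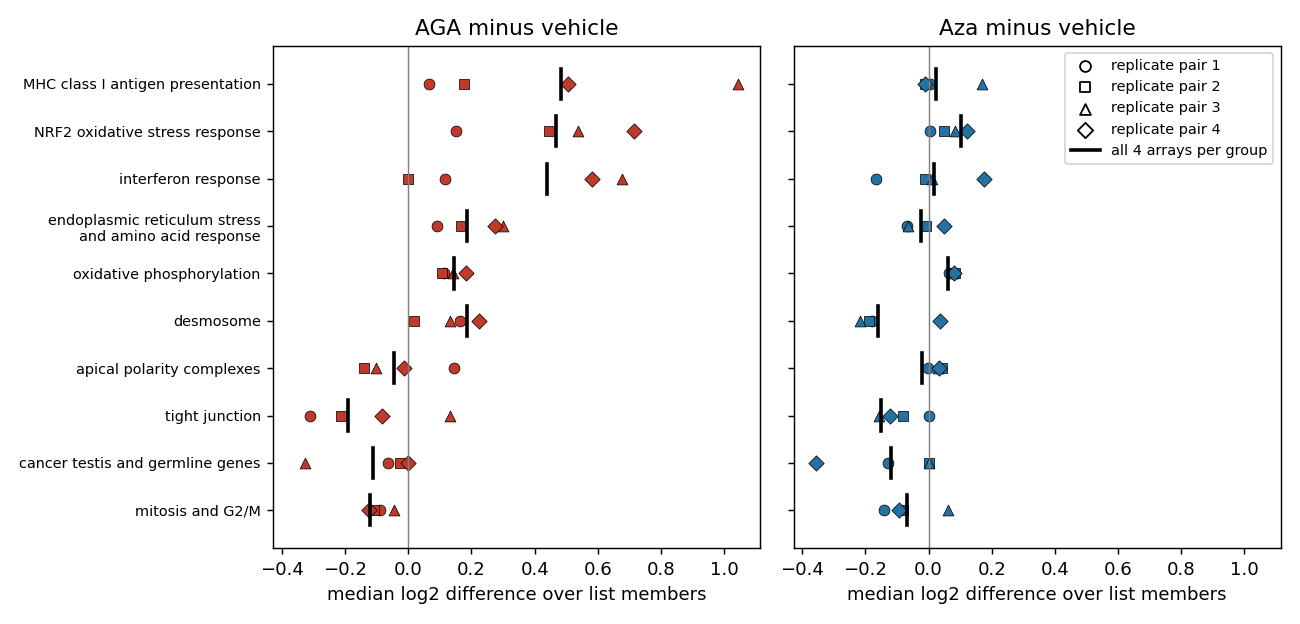
Median log2 difference over the members of 10 gene lists, AGA minus vehicle on the left and Aza minus vehicle on the right; each symbol is 1 same-number replicate pair and each bar the value over 4 arrays per group. The MHC class I symbols lie between 0.07 and 1.04 for AGA, and the median on the deposited scale, where all genes have a median of -0.24, falls below 0 for the stress and oxidative phosphorylation lists.

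With the replicate block and an intensity trend, a fit added after seeing the data, 156 probe sets passed in AGA against vehicle, 86 higher and 70 lower. Among them were the dim CYP1B1 (3.56) and KCNJ1 (2.80) probe sets given above (limma adjusted p = 0.0145 and 0.0391). The genes that follow were chosen above the median level, so they are not the largest changes. The lysosomal glycoprotein GPNMB rose by 1.66 ± 0.19 (SE of that fit, n = 4; limma adjusted p = 0.0014), and PSAP (0.65), NPC2 (0.64), CTSB (0.49) and PPT1 (0.42), whose products also act in lysosomes, passed. They were picked after their values were seen, no lysosome list was tested, and other probe sets of PSAP (0.11) and CTSB (-0.01) did not pass. SLC7A11, which imports cystine for glutathione, rose by 1.26 ± 0.21 (adjusted p = 0.0124), TXNRD1 by 0.76 ± 0.11 (0.00547) and the brightest CYP1B1 probe set by 0.94 ± 0.14 (0.00547). Amino acid transporter genes SLC7A5 (0.85) and SLC3A2 (0.64) and the stress pseudokinase TRIB3 (1.05) passed, as did the metal-binding metallothioneins MT1G (1.03 ± 0.15), MT1F, MT1E, MT2A and MT1X. All these metallothionein probe sets can cross-hybridise within the family, and another for MT1G was at -0.18. HLA-B (1.70 ± 0.24; adjusted p = 0.00533) and HLA-C (1.10) passed with 1 probe set each, which can also cross-hybridise, while the others were at 0.57 and 0.79 for HLA-B and at 0.51, 0.72 and 0.71 for HLA-C without passing. KRT16, a keratin of stressed epidermis, rose too (limma adjusted p = 0.0221), and UNC119, RANBP3 and IGFBP7 by 1.59, 1.28 and 1.22 (0.0432, 0.0428 and 0.0473). The UNC119, RANBP3 and IGFBP7 calls held in only 1 of 19, 4 of 20 and 5 of 20 other settings, against 17 of 20 for GPNMB. The amino acid transporter SLC38A4 fell by 2.00 ± 0.21 (adjusted p = 0.00113), the homeobox gene MSX1 by 2.18 ± 0.40 (0.0198) and the immediate early receptor NR4A1 by 1.72 (0.0428). The matrix protein gene THBS1 fell by 1.20 ± 0.21 (0.0158), the oestrogen sulfotransferase SULT1E1 by 0.79, and WDR48, SLITRK5 and EPHB6 by 1.41, 1.40 and 0.84. For IGFBP7 another probe set passed (0.69) and a dim one did not (-1.16), and for 4 of these genes the other probe sets did not pass: RANBP3 (-0.07, 0.03 and -0.15), WDR48 (-0.09, 0.30 and -0.19), NR4A1 (0.35 and -1.07) and THBS1 (-1.49 to 0.20).

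These calls depend on the fit and on the scale. All 156 kept their sign in every setting that tested them (152 were tested with dim probe sets left out), but the block alone left 2 and the trend alone 0. The block, the trend and the adjustment leave the differences unchanged and so cannot alter a sign. Of the 156, 77 were still called on the deposited scale and 127 on median-centred arrays. Without all replicate 4 arrays 31 were still called, and without AGA 3 26. On the deposited scale 322 passed, 11 higher and 311 lower, and on median-centred arrays 158, 109 higher and 49 lower. Counts moved by over 1.5 times without vehicle 1 (91), vehicle 2 (68), vehicle 3 (28), vehicle 4 (34), AGA 2 (102), AGA 3 (26), Aza 1 (100) or Aza 2 (95).

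**Figure D3:**
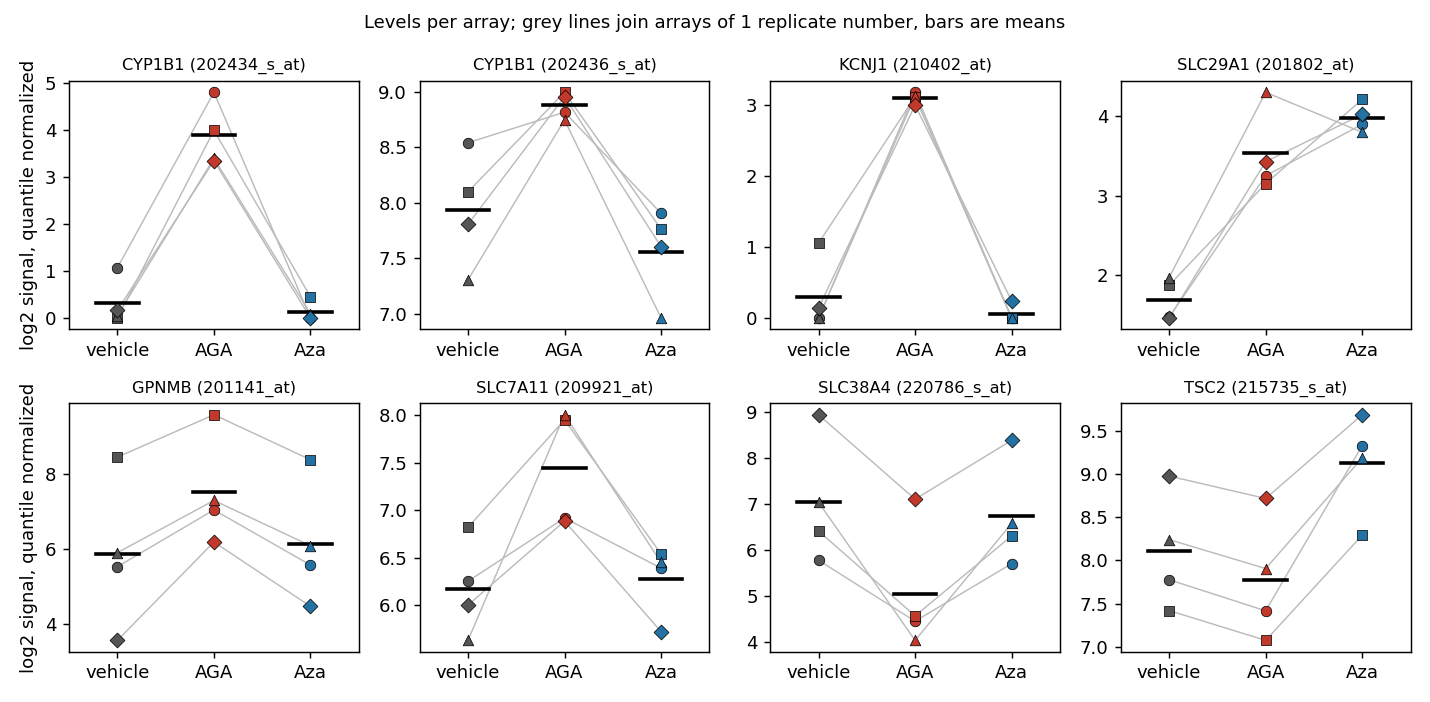
Log2 intensity of 8 probe sets on each array in the 3 groups; symbols mark replicate numbers, grey lines join arrays with the same number and bars are means of 4. GPNMB has means of 5.87 in vehicle, 7.53 in AGA and 6.14 in Aza, and TSC2 of 8.10, 7.78 and 9.12.

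Aza against vehicle asked which transcripts differ when DNA methylation is inhibited during acinus formation. SLC29A1, a nucleoside transporter that carries cytidine analogues, rose from 1.69 ± 0.27 to 3.98 ± 0.18 (SD, n = 4), by 2.30 ± 0.26 (SE; limma adjusted p = 0.0289, 0.481 with the replicate block). Another probe set of the gene differed by 0.01. Probe set 220899_at, which has no gene symbol here, fell by 2.73 ± 0.30 (adjusted p = 0.0289, 0.586 with the block). Below the threshold, the haematopoietic GTPase RHOH was 4.00 ± 0.59 higher (SE, n = 4; limma adjusted p = 0.196), with the mucin MUC4 at 2.71, from the floor on every vehicle array, the B cell receptor CD22 at 2.54 and the racemase AMACR at 3.24. The germ cell kinase AURKC was at -2.43, the immunoglobulin gene IGHM at -2.53, the channel subunit KCNE4 at -2.54, STUM at -2.16 and JAKMIP2 at -1.43, with adjusted p between 0.196 and 0.591. Other probe sets were at 0.42 and 0.83 for MUC4, 0.13, -1.20 and 0.59 for CD22, -0.76 for AMACR, which was brighter, and -0.96 to 0.08 for IGHM. With the block and trend, TSC2, a brake on mTOR signalling, rose by 1.02 ± 0.12 (SE of that fit, n = 4; limma adjusted p = 0.00793). Another TSC2 probe set differed by 0.97 without passing. The call was lost on the deposited scale (adjusted p = 0.0853), with the block alone (0.711), and without vehicle 1, vehicle 3 or Aza 3 (0 probe sets); 3 passed without vehicle 2, 2 without AGA 1, 4 without AGA 3 and 7 without Aza 2.

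The genes of the methyltransferases that Aza inhibits did not pass: DNMT1 differed by -0.28 ± 0.25, DNMT3A by -0.41 ± 1.07 and DNMT3B by -0.16 ± 0.41 (SE, n = 4; limma adjusted p of 1). HSD11B2 was 1.47 ± 0.70 higher in value and HSD11B1 -0.76. GJA1 (-0.23) and CDH1 (-0.29) were lower and ITGB4 (0.22) higher in 4 of 4 same-number pairs. None of these 3 passed with the replicate block (limma adjusted p of 0.912 to 0.928). PARD3 (-0.23), TJP1 (0.17), MKI67 (0.11) and CDKN1A (0.04) differed in direction between pairs. Cancer testis and germline genes, often silenced by methylation, had a median of -0.12, with 16 of 37 above 0 (camera adjusted p = 0.576), and PRAME was at -2.18. Imprinted genes had 0.01 (0.938) and methylation machinery -0.15 (0.576). Polarity and adhesion medians were -0.02 for apical polarity complexes, -0.15 for tight junction, -0.10 for adherens junction, -0.16 for desmosome, -0.07 for hemidesmosome and -0.23 for gap junction genes. Interferon (0.02), MHC class I (0.02), NRF2 (0.10) and stress genes (-0.02) had small medians. Camera called 0 of 34 lists, with the lowest adjusted p at 0.405 for oxidative phosphorylation (0.06; adjusted p = 0.977 with an estimated correlation), and limma gave 726 probe sets at an unadjusted p under 0.05. The unadjusted count was 1198 with the replicate block and 1438 with block and trend. The other 20 lists had camera adjusted p between 0.576 and 0.978. Without vehicle 3 oxidative phosphorylation genes passed, higher (0.0452), and without vehicle 4 immediate early genes, lower (0.00408); ribosomal protein genes passed, higher, on the deposited scale (0.00253). On median-centred arrays ribosomal protein genes (3.0e-09) and oxidative phosphorylation genes (0.0154) passed, and fry called 0 lists with or without the block. Mixed fry called 0 without the block and 4 with it: oxidative phosphorylation (adjusted p = 5.6e-04), fibroblast markers (0.00709), hemidesmosome and basement membrane (0.0282) and glucocorticoid response (0.0347). KIT, a luminal progenitor receptor, was 2.13 ± 0.42 higher and, without the block, the only member called adjusted over the list alone (adjusted p = 0.0102, limma; 0 over all probe sets); with the block DCN among fibroblast markers was called as well (0.0337). In all 2 probe sets passed, 1 higher and 1 lower. SLC29A1 and 220899_at both dropped out without vehicle 1, 2, 3 or 4, Aza 2 or Aza 3, SLC29A1 without AGA 4 or Aza 4, and 220899_at without AGA 3; the count ran from 0 (vehicle 2, 3, 4, Aza 2, 3) through 1 (vehicle 1, AGA 3) and 4 (AGA 1) to 7 (Aza 1). MUC4 passed without AGA 1 (0.0441) or AGA 4 (0.0392), and IGHM without AGA 1 (0.0441).

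Aza was set against AGA to test whether the effects of the treatments differed. CYP1B1 was lower in Aza by -3.75 ± 0.34 (SE, n = 4; limma adjusted p = 0.00438) and KCNJ1 by -3.04 ± 0.23 (0.00106). Both were near the floor in Aza (0.14 and 0.06), which sets these sizes; the brighter CYP1B1 probe sets were at -0.95, -1.32 and -1.13, and the other KCNJ1 probe set at -0.86. CASQ1, a calcium store protein, was at the floor on every AGA array and at 3.06 ± 0.51 in Aza (SD, n = 4; limma adjusted p = 0.0384, 0.184 with the replicate block, 0.0369 with block and trend). Below the threshold lay the oestrogen receptor GPER1 (3.63), CD22 (2.72), ONECUT2 (1.64) and TRIO (2.93) on the higher side, and TF (-2.44), IGLL5 (-1.36) and LGR5 (-2.42) on the lower, at adjusted p from 0.0755 to 0.209. With block and trend GPER1 passed (limma adjusted p = 0.0162) and the others did not. Other probe sets were at 0.79 for GPER1, -0.75, -1.36 and -0.32 for CD22, -0.18 to 0.61 for TRIO, -0.39 to 0.27 for TF, 1.01 for IGLL5 and 1.12 for LGR5. Limma called 3 probe sets, 1 higher and 2 lower, with 1058 at an unadjusted p under 0.05. The unadjusted count was 2029 with the replicate block and 2483 with block and trend. The CASQ1 call was lost without vehicle 2, vehicle 3 or any 1 of the AGA and Aza arrays (adjusted p of 0.0579 to 0.127), GPER1 passed without AGA 4 (0.0464) and TRIO without AGA 2 (0.0156), and 6 probe sets passed without AGA 2 and 7 without AGA 4.

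Camera called 6 lists lower in Aza than in AGA. Other ways of dividing these arrays gave 6, 7 and 8 lists, so chance division was not excluded. MHC class I genes had a median of -0.39, with 0 of 16 above 0 (camera adjusted p = 4.6e-06; 0.346 with an estimated correlation), and NRF2 targets -0.38 (8.4e-05; 0.47 with an estimated correlation). Interferon response genes had -0.39 (6.5e-04) and stress and amino acid genes -0.21 (0.00167), both with adjusted p = 0.47 with an estimated correlation. Desmosome genes had -0.27, with 1 of 14 above 0 (0.00207; adjusted p = 0.346 with an estimated correlation), led by EVPL (-1.44), PKP1 (-0.48), DSG2 (-0.47) and DSG3 (-0.57), which build epithelial adhesion plaques. Gap junction genes had -0.49, with 1 of 9 above 0 (0.00646; 0.276 with an estimated correlation), led by GJA3 (-1.02), GJA4 (-1.61) and GJB1 (-1.71). This list was dim, with a median level of 3.54 and 2 of 9 members above the median of all probe sets. It was too small to test with dim probe sets left out, and the bright GJA1 differed by -0.34 ± 0.36 (SE, n = 4). The block added oxidative phosphorylation at -0.07 (0.014 with the block, 0.127 without; adjusted p = 0.363 with an estimated correlation and the block), which also passed without AGA 2 (0.0186) or Aza 3 (0.012) but has 0.11 on the deposited scale, where all genes have a median of 0.18. The interferon list was lost without AGA 3 (0.132) and the stress list without Aza 4 (0.0936), while NF-kB genes passed without AGA 2 (0.021). Without the block limma called 0 members of the 6 lists over all probe sets, and adjusted over the list alone 0; DCN among fibroblast markers (0.0222) and MAGEA12 among cancer testis genes (0.039) passed adjusted over the list alone. With the block, 5 NRF2 members (ME1, SLC7A11, EPHX1, GCLC and PIR) and 5 stress members (PHGDH, TRIB3, SLC3A2, SLC7A11 and ASNS) were lower adjusted over the list alone, as were MT1G, MT1X and MT1F, COL4A1 and COL4A2, P4HA2 and LAPTM5, while NID1, CDKN1C, FASN and KDR were higher. Over all probe sets the block with trend called 3 NRF2, 4 stress and 1 desmosome member lower. Fry with the block called oxidative phosphorylation (0.0466), and mixed fry 24 of 34 lists, against 0 without the block. The other 28 lists had camera adjusted p between 0.127 and 0.978.

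With block and trend, 189 probe sets passed in Aza against AGA, 104 higher and 85 lower. Among them were dim probe sets of CYP1B1 (-3.75), KCNJ1 (-3.04), GPER1 (3.63) and CASQ1 (3.06). The genes that follow were chosen above the median level. MSX1 was higher in Aza by 2.93 ± 0.40 (SE of that fit, n = 4; limma adjusted p = 0.00187), TSC2 by 1.35 ± 0.12 (1.7e-04), SLC38A4 by 1.70 ± 0.21 (9.7e-04) and the lipid droplet protein CIDEC by 1.49 ± 0.22 (0.00375). RAB40A (1.83), RBP4 (1.52), the matrix proteoglycan DCN (1.47) and MYOT (1.28) were also higher. The carbonyl reductase CBR3, an NRF2 target, was lower by -2.69 ± 0.50 (0.0142), GPNMB by -1.40 ± 0.19 (0.00178), the brightest CYP1B1 probe set by -1.32 ± 0.14 (4.3e-04), and RRAGD, which signals amino acids at the lysosome, by -2.29. CTSH (-1.46), HLA-B (-1.42), FAT2 (-1.36) and KRT16 (-1.27) followed. Other probe sets of DCN (0.16 to 1.59), RBP4 (-1.27), RRAGD (-1.50), TSC2 (-0.84) and HLA-B (-0.56 and -0.71) did not pass. On the deposited scale 159 passed, 142 higher and 17 lower. The count was 65 without AGA 3, 124 without AGA 4, and 80, 89, 55 and 108 without Aza 1, 2, 3 and 4.

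Changes common to both treatments were sought because both remove polarity. Limma called 0 probe sets in the same direction in both, with 1 when vehicle 1 or Aza 1 was left out. At an unadjusted p under 0.05, 100 probe sets were higher in both (8.82 for independent lists), 73 lower in both (8.36) and 7 opposite. Simulated unchanged groups sharing the vehicle arrays gave 40.7, 54.8 and 1.33, but from shorter lists (2.10 and 2.08 for independent lists), so these are not the values without change for lists of the observed length. Among the 100 and 73 were LRRC20 (0.60 in AGA, 0.58 in Aza), the surface antigen PSCA (0.66, 1.14), TTC12 (0.62, 0.57) and SSX2IP (0.69, 0.62), and on the lower side the acetyltransferase EP300 (-0.54, -0.50), POLR3F (-0.78, -0.79), ZNF711 (-0.71, -0.55) and RIOK3 (-0.85, -1.20), all with limma adjusted p of 0.803 or more. Across probe sets, which are not independent replicates, the changes correlated at 0.451, against 0.5 in simulation. Their covariance was 0.131 against 0.118 (0.111 to 0.125), a difference of 0.0135. With 2 vehicle arrays for each treatment the mean correlation was -0.048, and with separate same-number pairs 0.00277. Above the median level these were -0.227 and 0.059 (0.00282 to 0.118), and with the shared arrays 0.379, against 0.502 in simulation (0.469 to 0.526). For the mean of both treatments, SLC29A1 was the 1 probe set called, higher by 2.07 ± 0.22 (SE; limma adjusted p = 0.0392, 0.365 with the replicate block), with 771 at an unadjusted p under 0.05 (1483 with the block). Its other probe set differed by -0.36 in AGA and 0.01 in Aza. The number called was 0 without vehicle 3, vehicle 4, AGA 2, AGA 4, Aza 2, Aza 3 or Aza 4, and 2 without AGA 1. With block and trend 0 passed (1906 unadjusted); the lowest adjusted p, 0.0739, belonged to CCDC51 (0.47), SLC38A4 (-1.15), CSTB (0.41), RHOH (3.23) and GPNMB (0.97).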

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

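The tests of array brightness and the divisions of arrays under the fit with block and trend were chosen after the results they test were seen.

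The replicate 4 arrays of all 3 groups stood apart on the first principal component, with AGA 4 at 38.75 and Aza 4 at 46.29 against at most -7.324 for the others. RNA degradation was tested by the 3' to 5' ratio of ACTB and GAPDH probe sets, which it would raise. For ACTB 3 of 3 replicate 4 arrays lay within the range of the other 9. For GAPDH 1 did, the lowest being at 0.194 against 0.216 in the others. For both transcripts 0 lay above the range, which excluded degradation as far as these ratios measure it. For array brightness, the same-number correlations of replicate 4 were at least 0.735 after quantile normalization. The pattern itself was seen on normalized values, so this test could not decide. The deposited medians of the 3 replicate 4 arrays (29.6, 25.6 and 25.5) lay within the range of the other 9 (23.3 to 35.9). A separate batch of cells, medium or gel could have this form, but no label records one. No biological explanation was tested, and the cause stays open.

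The 5 gene lists called higher in AGA were tested against 3 technical explanations, with their members pooled. For the pooled members, a single replicate pair and cross-hybridisation alone were excluded. The test was not run list by list, so cross-hybridisation stays open for single lists such as MHC class I. The pooled members were above 0.1 in 4 of 4 same-number pairs, only just so in pair 1 (0.10, 0.16, 0.33 and 0.32), and the interferon (0.12, 0.00, 0.68 and 0.58) and MHC class I medians (0.07, 0.18, 1.04 and 0.51) came mostly from pairs 3 and 4. Scaling stays open: the median relative to all genes was 1.11 times as large on the other scales, but a shift common to an array cannot alter that value, and on the deposited scale the stress (-0.07) and oxidative phosphorylation medians (-0.08, not called at 0.193) were below 0. Members measured by probe sets without cross-hybridising design had a median of 0.21, against 0.24 for the rest. Chance division of the arrays was not excluded (9 of 35 ways), so a stress response to AGA may be real only as a hypothesis, which independent cultures could test.

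Cancer testis and germline genes were not called higher in Aza, although such genes are often demethylated by it. Arrays that could not show a rise of single members were not excluded: the list's median level was 1.65, with 2 of 37 members above the median of all probe sets, and 1.76% of members were called when their signal was raised 4-fold in simulation. As a list, that rise of the signal of all 37 was called by camera at its preset correlation in 20 of 20 simulations. The rise was added after the floor was applied and to independent genes. The result therefore covers only a common shift of that size in the floored values. How far a transcript this dim moves its signal was not tested, so a rise of transcripts could have been missed.

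Chance division of the arrays was not excluded for the numbers of probe sets without the block. In AGA against vehicle 11 of 35 ways gave as many (real 2, highest other 3), in Aza against vehicle 10 of 35 (2 and 5) and in Aza against AGA 6 of 35 (3 and 4). Among the 8 ways that part all same-number pairs the highest other counts were 2, 5 and 4. For not polarized against polarized, 55 of 100 ways gave as many (1 and 11). There, 4 ways called at least 5 times the real number, and those parted 0 to 2 of the same-number pairs. The 17 that part all 4 pairs gave 4 at most. Most of the 100 ways part 0 to 2 pairs, so these counts alone cannot show a structure of the samples. For the lists in AGA, 9 of 35 ways gave as many (5 and 8, or 7 among those that part all pairs). A division with 8 lists set replicates 1 and 2 against 3 and 4. The other divisions purely by replicate number gave 1 and 4 lists, and another with 8 parted 2 of the pairs. These counts therefore do not show a structure by replicate number. With block and trend only 8 ways exist, too few for a share under 0.05: in AGA 1 way gave as many (156, highest other 0), in Aza 2 (1 and 1) and in Aza against AGA 1 (189 and 0).

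Single arrays apart from the other 3 of their group were found in 11 of 92 groups, where chance gives 4.6, about 1 in 20. That rate assumes values without a floor. Where the other 3 arrays lie at the floor, any higher value counts, as for KCNJ1 in Aza 4 and HSD11B2 in vehicle 2. The number above 4.6 can therefore come partly from the floor. The deposited log2 median was 5.164 for vehicle 3 (others 4.886 to 4.899) and 4.67 for Aza 4 (4.918 to 4.954). The mean of the endoplasmic reticulum stress list was 7.074 in vehicle 4, against 7.369 to 7.407. CYP1B1 was at 1.069 in vehicle 1, against 0 to 0.1638. KCNJ1 was at 1.052 in vehicle 2, against 0 to 0.1397, and at 0.2396 in Aza 4, against 0. DNMT3A was at 0 in AGA 3, against 3.144 to 3.588. HSD11B2 was at 0.5652 in vehicle 2, against 0. MKI67 was at 3.117 in AGA 3, against 4.356 to 4.581.

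The effects of the treatments were tested against each other, and these were called in Aza minus AGA. CYP1B1 differed by -3.75 and KCNJ1 by -3.04. CASQ1 differed by 3.06 (limma adjusted p = 0.184 with the replicate block, 0.0369 with block and trend). The desmosome list had -0.27 (adjusted p = 0.346 with an estimated correlation) and the gap junction list -0.49 (0.276 with an estimated correlation, and 0.0549 without replicate 4). Only 2 of 9 gap junction members lay above the median level of all probe sets. The interferon, MHC class I and NRF2 lists had -0.39, -0.39 and -0.38 (adjusted p = 0.47, 0.346 and 0.47 with an estimated correlation), and the stress and amino acid list -0.21 (0.47). The interferon call was also lost without AGA 3 (0.132) and the stress call without Aza 4 (0.0936).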

How the results depend on the processing

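Every probe set called without the block lay below the median level, where simulations recovered few changes. Leaving out dim probe sets gave 0 in AGA, 0 in Aza, 0 in Aza against AGA and 0 in not polarized against polarized, because the probe sets called were among those removed. The intensity trend also gave 0 in each. The deposited scale gave 0 in not polarized against polarized, and median-centred arrays gave 0 in Aza. A floor at the 20th percentile gave 0 in Aza, 5 in Aza against AGA and 2 in not polarized against polarized. Holm adjustment gave 1 in Aza, and a threshold of 0.01 gave 0 in Aza and 0 in not polarized against polarized. Fitting only the 2 groups compared gave 5 in AGA and 4 in Aza. Leaving out all replicate 4 arrays gave 7 in AGA, 6 in Aza, 8 in Aza against AGA, 2 in not polarized against polarized and 2 called the same way in both treatments. The causes were not tested.

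With the replicate block, which pairs the same numbers, 0 passed in Aza and 0 in not polarized against polarized, and 2 in AGA and 2 in Aza against AGA; the block changed no call other than those given with the genes and lists above. With block and trend, 156 passed in AGA, 1 in Aza, 189 in Aza against AGA and 0 in not polarized against polarized. With the block and dim probe sets left out, 0 passed in AGA, 0 in Aza, 83 in Aza against AGA and 0 in not polarized against polarized, and with the trend added 241, 1, 257 and 0.

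The correlation of the 2 treatments' changes was reversed when each treatment had its own 2 vehicle arrays, at -0.0488, -0.0395, -0.0400, -0.0302, -0.0515 and -0.0779. In those divisions all 4 treated arrays met only 2 replicate numbers of vehicle, so the pairing was broken. With separate same-number pairs it was 0.0026, 0.0074, -0.00196, 0.00435, -0.0037 and 0.00794.

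With block and trend, the deposited scale gave 322 in AGA, median-centred arrays 158 and 3 in AGA and Aza, and Holm adjustment 9 in AGA and 20 in Aza against AGA. Without block or trend 2 remained in AGA, 2 in Aza and 3 in Aza against AGA; with the block alone 2, 0 and 2; and with the trend alone 0, 0 and 0. Leaving out all replicate 4 arrays gave 44, 2 and 90, and leaving out 1 array at a time 26 to 232 in AGA (lowest without AGA 3, highest without AGA 1), 0 to 7 in Aza and 55 to 231 in Aza against AGA (lowest without Aza 3, highest without AGA 1). Leaving out 1 array gave 1 to 5 in AGA, 0 to 7 in Aza, 2 to 7 in Aza against AGA, 0 to 2 in not polarized against polarized and 0 to 1 in both treatments without block and trend.

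Camera with an estimated correlation called 0 lists in AGA and 0 in Aza against AGA, with or without the block. The deposited scale gave 1 list in Aza, median-centred arrays gave 2, and leaving out 1 array gave 0 to 1. The ribosomal protein list in AGA was reversed on median-centred arrays, at 0.19. The gap junction list in Aza against AGA was not called without all replicate 4 arrays (adjusted p = 0.0549). Leaving out 1 array, 1100 list values stayed the same, 112 moved, 9 gained a call and 3 lost it; in the other settings 700 stayed, 63 moved, 1 reversed, 10 gained a call and 24 lost it. For the named genes 718 stayed, 48 moved, 9 gained a call and 29 lost it on leaving out 1 array, and 549, 17, 7 and 26 in the other settings. For genes of the fit with block and trend, 287 stayed and 109 lost the call on leaving out 1 array, and 111 and 145 in the other settings.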

Other observations

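The comparison of replicate 4 with the other replicates was chosen after the arrays were seen. Across the 3 groups, limma called 2686 probe sets in replicate 4 against replicates 1 to 3, 1245 higher and 1441 lower. That fit took the 3 replicate 4 arrays as separate samples, although same-number arrays were treated as paired elsewhere. Its p-values therefore do not measure variation between replicates. The same comparison called 10, 1 and 0 for replicates 1, 2 and 3. In those fits the replicate 4 arrays were among the others and widened the spread, so the counts cannot show that replicates 1 to 3 hardly differ. Their same-number arrays correlated at 0.368 to 0.596. Higher genes included BEX1 (4.29), CRISPLD2 (4.10), the basement membrane gene NID1 (2.92) and the calcium-binding S100A8 (2.80). Lower genes included the growth factor binding protein IGFBP2 (-5.58), EYA1 (-5.22), the immediate early gene EGR1 (-4.19), OMD (-3.45) and the growth hormone receptor GHR (-3.11). SLC38A4, KRT16 and NR4A1, which passed in AGA with block and trend, also differed in replicate 4.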
